A study of Homo sapiens with 60 samples.

How the data were processed

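The series holds 60 samples. They comprise 27 in situ Hi-C libraries, 5 capture Hi-C libraries, 5 Capture-C libraries, 20 ChIP-seq peak lists and 3 RNA-seq samples. In situ Hi-C ligates chromatin ends that lie close together in fixed nuclei, so that the number of ligated read pairs between 2 genomic bins measures how often they are in contact. T47D, MCF7 and BT474 are breast cancer lines that express the estrogen receptor (ER) and the progesterone receptor (PR); MCF10 is a mammary epithelial line and SKBR3 a breast cancer line with amplified ERBB2. SKBR3 and MCF10 were compared as the receptor-negative lines; both SKBR3 libraries and MCF10 library 1 are labelled as lacking the receptors. Per the labels' protocols, T47D cells were kept without steroids and then overnight without serum, and were either collected untreated (T0) or given 10 nM of a progestin (R) or of estradiol (E) for the stated minutes.

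The deposited Hi-C, capture Hi-C and Capture-C files give raw contact counts per pair of 100 kb bins on the same chromosome, with the contacts inside a bin counted double, as checked from the values. Contacts between chromosomes were not in these matrices and were not analysed here. The digestion enzyme is MboI in the labels of replicate 1 and DpnII in those of replicates 2 and 3, and both enzymes cut the same site. The ChIP-seq files are peak lists, 1 per sample, and hold the score, the fold enrichment (ratio) and the −log10 p and q values that the authors deposited for each peak. The layout is that of MACS2 output, but the caller, the aligner and their settings are not given in the sources used here. The genome build was hg38 per the submitters' processing notes. Peak scores and folds are the authors' values and were used only to describe or filter peaks within a list.

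Bins were kept when their contacts reached 10% of the chromosome median in the libraries, which left 27936 of 30312 bins. Each library was balanced over 40 rounds. A compartment score was the mean log2 observed over expected contact of a bin with reference A bins minus that with reference B bins of the same chromosome, at distances over 0.2 Mb. A is the open, gene-rich compartment and B the closed one, so a higher score means more contact with open chromatin. An insulation score was the log2 mean balanced contact across a bin within a 500 kb window, relative to the chromosome (27333 bins). Lower insulation values mark stronger boundaries. Single contacts were tested as raw counts of bin pairs 0.1 to 2 Mb apart with a mean of at least 10 per library.

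Hormone comparisons used all 15 T47D hormone libraries, 3 in each of 5 groups, in 1 fit. The sequencing batch in the labels entered as a block. Scores were tested with limma 3.58.1 and bin pairs with edgeR 4.0.16 (quasi-likelihood F test with an offset for each library's contacts at the same distance), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences below come from these fits and are ranked by them. They can differ from the difference of the plain group means, since R180 replicate 2 lies in a batch without a T0 library. The pairing was checked on the compartment score: libraries with the same replicate number deviated together from their group means, with correlations of 0.311 to 0.503 for number 1, 0.11 to 0.208 for number 2 and 0.0984 to 0.176 for number 3, against a median of −0.224 between different numbers. The block rests on the batch in the labels, not on this check. Line comparisons used 1 mean or sum per line, 3 lines against 2, with limma and edgeR. The knockdown libraries, the capture libraries and most peak lists have 1 library per condition and were not tested.

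Replicates 2 and 3 of a hormone group differed by 1.22 to 1.29 chi-square units per degree of freedom over bin pairs of chromosome 6, against 1.29 to 1.47 between replicate 1 and either of them. Libraries of different groups differed by as little as 1.20 within a batch and 1.24 between batches. Thinned to the same depth, replicates 2 and 3 of a group differed by 1.15 (T0) to 1.2 (R180), against 1.13 to 1.28 for libraries of different groups and batches. Replicates 2 and 3 were thus closer to each other than to replicate 1, but beyond counting noise and not closer than all libraries of different groups. This comparison fits out distance and leaves out contacts inside a bin. In replicates 2 and 3 those made up 24.3% and 24.3% at T0, 28.5% and 28.6% at R30 and 24.9% and 24.8% at R180. They made up 28.2% and 27.9% at E30 and 24.6% and 24.3% at E180. Replicates 2 and 3 were kept as separate samples, and fits with the pair averaged or summed were added after seeing the data. The splits of a Capture-C sample differed by less than sampling noise (0.548 and 0.431) and were counted as 1 sample. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

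Gene positions came from the RefSeq table of GRCh38. It gives no strand, so the bin of a gene was the bin holding its midpoint rather than its transcription start, and a peak was near a gene when it lay within 20 kb of the gene body. Before the data were examined, 12 gene lists were fixed: estrogen-induced genes (40), progestin- or glucocorticoid-induced genes (30), luminal markers (24), basal and mesenchymal markers (30), receptors and cofactors (22), the ERBB2 amplicon (14), architectural proteins (16), cell cycle genes (19), housekeeping genes (16), and markers of blood cells (14), of fibroblasts and endothelium (15) and of neurons (12). A further list of 12 genes was to be named whatever their values. CDH1 and CDH3 lay in a bin that was left out. List shifts were tested with camera in limma (preset correlation 0.01). The named-genes rule, also fixed beforehand, takes for each test the 10 largest rises and 10 largest falls past the threshold with the same sign in every batch, 1 per run of adjacent bins, then up to 4 members of each list whose bin passes, and the 12 genes above.

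Receptor cluster bins were bins with at least 3 T47D ER peaks (medium with phenol red) and at least 3 MCF7 PR peaks (progestin), where 3 was the smallest number that gave at most 300 bins. Each was matched to up to 5 control bins in T47D H3K27ac peaks, compartment score and coverage. The match was incomplete for H3K27ac, with a relative value of 5.84 in cluster bins against 3.86 in control bins. Cluster bins held 1.27 genes per bin against 1.86. Enrichment was the log2 contact among cluster bins over 2 Mb apart minus that among control bins. It was compared by exact permutation tests, which take no account of batch.

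The scripts were tested on simulated data drawn from the real libraries. For the hormone bin pairs, 1.49% of pairs changed 1.3-fold were recovered, 20.9% at 1.6-fold and 60.6% at 2.5-fold. False calls numbered 6 in that simulation. It drew each library independently with the fitted trend in spread, and planted no likeness between replicates 2 and 3. Its false calls therefore give no rate for the real libraries. For the hormone compartment score, 11.9% of bins changed by 0.33, 71.6% changed by 0.65 and 100% changed by 1.09 were recovered. The corresponding insulation shares were 5.97%, 82.1% and 100% at 0.11, 0.22 and 0.37. False calls numbered 8 for the compartment score and 5 for insulation. For the line comparison, 37.3% of bins changed by 2.92 were recovered on the compartment score. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with DESeq2 1.42.0 as an alternative test of the counts, were used.

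The alternatives covered the block, the window, the distance range, the first eigenvector, the normalization, the count filter, the peak threshold and overlap, and leaving out each library in turn. With the batch as a block, leaving out the only T0 library of a batch also removes that batch's differences from T0. Such a fit therefore loses more than a single library. The 3 RNA-seq samples have no file here and were not analysed here. A Pol II sample whose title and characteristics name different conditions was put in no group. The label of MCF10 library 2 says ER+/PR+, unlike that of library 1, and the comparison was repeated without it.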

Results

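The data describe chromosome contacts in T47D cells at T0, after 30 and 180 min of progestin (R30, R180) and after 30 and 180 min of estradiol (E30, E180), with 3 Hi-C libraries per group. Untreated Hi-C libraries of MCF7, BT474, MCF10 and SKBR3 (2 each) and T47D libraries with PR or ER depleted (1 each, with 1 control each) complete the Hi-C set. The hormone libraries held 39082372 (R180 replicate 3) to 152992983 contacts (E30 replicate 1), and the other Hi-C libraries 78037195 to 143753286. On the compartment score, hormone libraries correlated across bins at 0.983 to 0.994, libraries of the same other line at 0.963 to 0.986 and libraries of different lines at 0.757 to 0.864. Capture Hi-C libraries held 3867181 to 11895281 contacts and Capture-C libraries 3358194 to 4481471. The peak lists cover ER and PR in MCF7, ER, BRD4, H3K27ac and Pol II in T47D, and CTCF in a GM line.

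Which regions changed compartment when T47D cells received progestin was asked first. After 180 min the bin of ZBTB16, a transcriptional repressor gene known to be induced by progestins and glucocorticoids, rose in compartment score from 1.10 ± 0.076 to 1.75 ± 0.096 (SD, n = 3; chromosome 11, 114100001 to 114200000; difference 0.71 ± 0.082 SE, limma adjusted p = 0.00454). The bin of FKBP5, which encodes a co-chaperone of steroid receptors and is also hormone-induced, fell from 1.83 ± 0.22 to 0.79 ± 0.072 (chromosome 6, 35600001 to 35700000; difference −1.08 ± 0.12 SE, limma adjusted p = 0.00412). Both differences had the same sign in both batches that held T0 and R180 libraries (0.68 and 0.79 for ZBTB16, −0.80 and −1.30 for FKBP5). At E180 the same bins differed from T0 by 0.13 (ZBTB16, limma adjusted p = 0.864) and −0.13 (FKBP5, limma adjusted p = 0.914).

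Other bins that rose at R180 held TG, the thyroglobulin gene (0.85, chromosome 8, 132900001 to 133000000, from −0.69 ± 0.089 to 0.16 ± 0.082). They also held PREX1, which encodes a Rac exchange factor (0.75, chromosome 20, 48700001 to 48800000), ATP10A, a phospholipid flippase gene (0.78), and the acyl-CoA synthetase genes ACSM1 and ACSM3 (0.74). Rises of 0.66 to 0.71 were found at AKAP4, at EAF2 with IQCB1 and SLC15A2, and at ZNF385B. Falls were found at GRHL2 with NCALD (−0.89, chromosome 8, 101600001 to 101700000), where GRHL2 encodes an epithelial transcription factor. Falls also lay at LDLRAD4, a regulator of TGF-β signalling (−0.87), at KCNMA1, a calcium-activated potassium channel gene (−0.81, chromosome 10, 77300001 to 77400000), and at the tumour suppressor gene WWOX (−0.68). The limma adjusted p of these bins ranged from 0.0016 (TG) to 0.0324 (ATP10A). The fall with the largest fitted difference, −1.42, was in a bin without a protein-coding gene on chromosome 22 (16300001 to 16400000), where the group means were −3.71 and −2.75 and the differences within batches −0.89 and −1.65. By group means FKBP5 fell further.

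In all, 114 bins rose and 78 fell at R180 (limma, 192 of 27936 bins, with 4084 at unadjusted p under 0.05). All 192 had the same sign in both batches, but the fit that chose them used these batches. The rises lay in 94 runs of adjacent bins on 21 chromosomes with a median size of 0.51. In compartment A at T0 were 36.8% of the bins that rose and 70.5% of those that fell, against 52.9% of all bins in untreated T47D. The same T0 libraries set this state and enter the difference. Selection of rises therefore favours low T0 scores and that of falls high ones. No bin passed at R30 (2139 at unadjusted p under 0.05), E30 (1480) or E180 (1732) with limma, the only tool run on the scores. At R30 the FKBP5 bin differed by −0.58 ± 0.11 (SE, limma adjusted p = 0.378) and the ZBTB16 bin by 0.43 ± 0.074 (SE, limma adjusted p = 0.314). The R180 count depended on the library left out. It was 1 without T0 replicate 2, 7 without T0 replicate 1, 33 without R180 replicate 3, and 34 without R180 replicate 1. It was 71 without T0 replicate 3 or R30 replicate 3, and 86 to 108 without R180 replicate 2, E30 replicate 1 or 2, or any E180 replicate. T0 replicate 3 and R30 replicate 3 share a batch with no other hormone library, so leaving out either takes both out of the contrasts. For E30 the count was 1 without E30 replicate 2 or R180 replicate 3, and for E180 it was 1 without E30 replicate 2.

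**Figure D1:**
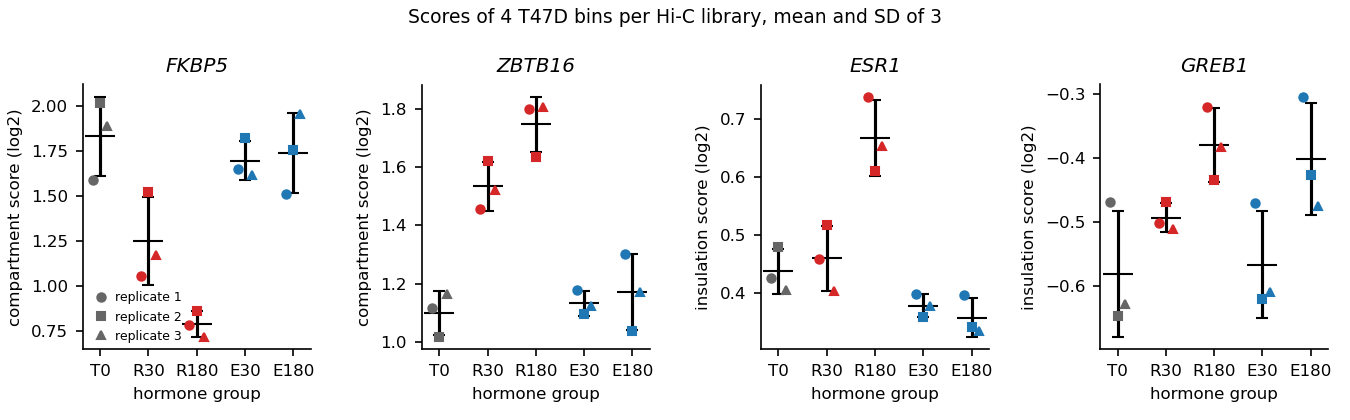
Compartment score (log2, the FKBP5 and ZBTB16 bins) and insulation score (log2, the ESR1 and GREB1 bins) of each T47D Hi-C library by hormone group, with replicates 1 to 3 as circles, squares and triangles and the mean and SD of 3 as bars. The R180 means are 0.79 (FKBP5), 1.75 (ZBTB16), 0.67 (ESR1) and −0.38 (GREB1), against 1.83, 1.10, 0.44 and −0.58 at T0.

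**Figure D2:**
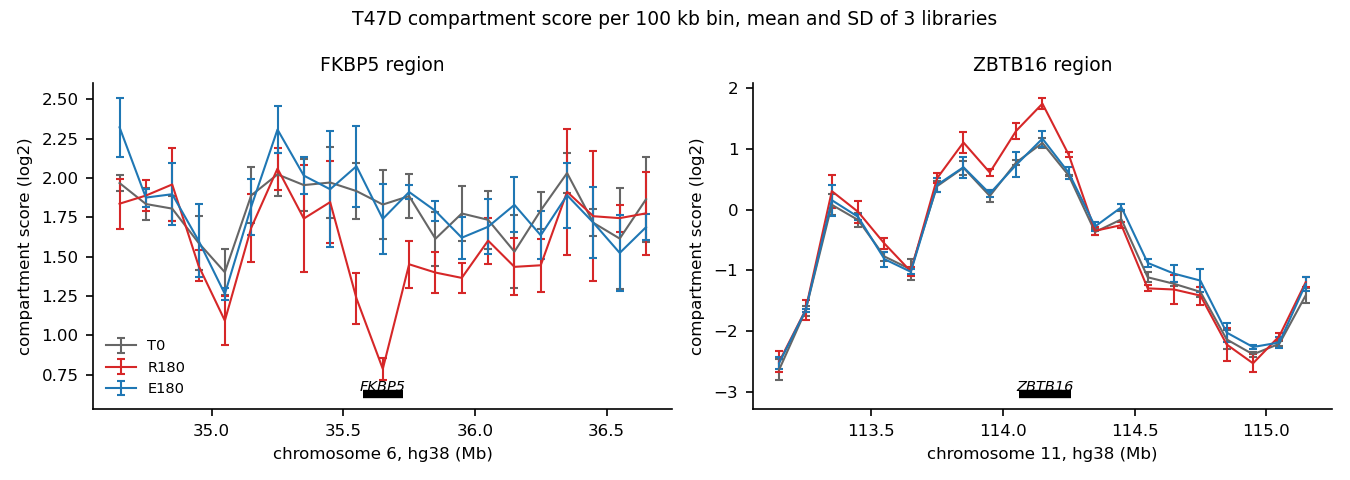
Compartment score (log2) per 100 kb bin along the FKBP5 region of chromosome 6 and the ZBTB16 region of chromosome 11 (hg38, Mb), as mean and SD of 3 libraries at T0, R180 and E180, with the gene bodies as black bars. The R180 line leaves the T0 and E180 lines at FKBP5, where its mean is 0.79 against 1.83 at T0, and at ZBTB16, where it is 1.75 against 1.10.

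Among the fixed lists, the progestin- or glucocorticoid-induced genes were the only ones with a bin past the genome-wide threshold on the compartment score at R180. Of their 29 bins, ZBTB16 rose and FKBP5 fell; adjusted over the list alone, 3 rose and 2 fell. Adjusted over the list alone, none of the other 11 lists had a bin that passed at R180. At R30, 3 progestin-induced bins rose and 1 fell when adjusted over the list alone, as did 1 bin each of the ERBB2 amplicon, the fibroblast and endothelial markers and the receptors and cofactors, all rising. At E30, 1 of 39 estrogen-induced bins fell when adjusted over the list alone. With their own bins, no list shifted as a whole in any hormone comparison on either score (camera in limma; the lowest adjusted p was 0.112, for the blood markers at E180). With 1 bin added on each side of each gene's bin, the progestin-induced genes shifted up on the compartment score at R30 and R180 (medians 0.05 and 0.08, camera adjusted p = 0.0321 and 0.0414; 0.577 and 0.601 with their own bins). The blood markers then shifted down on the compartment score at E30 and E180 (medians −0.06 and −0.10, camera adjusted p = 0.0353 and 0.00355) and on insulation at E30 (−0.02, camera adjusted p = 0.0371). With an estimated correlation and their own bins the adjusted p of each of these was 0.986. Scores of adjoining bins may vary together, whereas the preset correlation treats them as nearly independent. The p-values with added bins may therefore be too low. The bin of GREB1, an estrogen-induced gene, differed by −0.25 at R180 (limma adjusted p = 0.236) and that of PGR, which encodes PR, by 0.15 (limma adjusted p = 0.466). The bins of CCND1, ERBB2, ESR1, FOXA1, GATA3, KRT5, MYC and TFF1 differed by −0.15 (CCND1) to 0.31 (TFF1) at R180, with limma adjusted p from 0.298 (FOXA1) to 0.93 (KRT5).

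Insulation was compared to ask where contact across a position changed. At R180 contact rose across the bin of ESR1, the ER gene, from 0.44 ± 0.039 to 0.67 ± 0.065 (SD, n = 3; chromosome 6, 151800001 to 151900000; difference 0.22 ± 0.034 SE, limma adjusted p = 0.0077). It also rose across GREB1 (0.21 ± 0.04 SE, limma adjusted p = 0.0242, chromosome 2, 11500001 to 11600000) and across NDRG1, a stress- and hormone-responsive gene (0.23 ± 0.029 SE, limma adjusted p = 0.00297, chromosome 8, 133200001 to 133300000). After 180 min of estradiol GREB1 differed from T0 by 0.19 ± 0.04 (SE, limma adjusted p = 0.451), with 0.16 and 0.17 in the separate batches. R180 and E180 differed by 0.02 at GREB1 (limma adjusted p = 0.808), and by 0.31 at ESR1 (limma adjusted p = 0.000259), where E180 minus T0 was −0.09 (limma adjusted p = 0.675). Contact fell across KRT7, a luminal keratin gene (−0.14 ± 0.029 SE, limma adjusted p = 0.0376), and across a KCNMA1 bin (−0.32 ± 0.031 SE, limma adjusted p = 0.000902, chromosome 10, 77600001 to 77700000). The GATA3 bin, which holds the gene of a luminal transcription factor, differed by −0.12 (limma adjusted p = 0.0694). The other 9 of the 12 genes named whatever their values differed by −0.05 (CCND1) to 0.09 (FKBP5), with limma adjusted p from 0.128 (FKBP5) to 0.985 (TFF1).

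By fitted difference, the largest insulation rises at R180 were at L1TD1 with the cell polarity gene PATJ (0.36), FAM114A2 (0.34), REPS2 (0.30), EOLA1 (0.30) and ACOXL with BCL2L11, which encodes a pro-apoptotic protein (0.30). Next came TTC6, a neighbour of FOXA1 (0.29), NRXN1 (0.28), the kinase gene MAST4 (0.28) and GPSM2 (0.28). The largest falls were at SCEL (−0.41), ACOD1 with CLN5 (−0.35), TMEM255A with ZBTB33 (−0.35), SLC25A26 (−0.35), ARL1 with UTP20 (−0.33), the ubiquitin ligase gene UBE3A (−0.32), DDC with the lymphoid factor gene IKZF1 (−0.29), the Wnt receptor gene FZD8 (−0.29) and NCAM2 (−0.28). Together 126 bins rose and 160 fell (limma, 286 of 27333; 3785 at unadjusted p under 0.05), with median sizes of 0.17 and −0.18, and 6 bins passed on both scores.

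By list, 1 of 38 estrogen-induced bins rose at R180 (adjusted over the list alone, 1 rose and 1 fell), and 1 of 29 progestin-induced bins rose (3 rose). Of the luminal markers, 1 of 22 bins rose and 1 fell (1 rose and 3 fell), and 1 of 22 bins of receptors and cofactors rose (1 rose and 1 fell). In both of these lists the bin that rose over all bins was the same one, that of ESR1. No bin of the architectural proteins or cell cycle genes passed over all bins; adjusted over the list alone, 2 of 16 architectural bins rose and 1 fell, and 2 of 18 cell cycle bins fell. The other 6 lists had 0 by either count. After 30 min of progestin contact fell across 6 bins in 4 runs and rose across 0 (limma; 2710 at unadjusted p under 0.05), among them ZNF608 (from 0.33 to 0.07, −0.26 ± 0.03 SE, limma adjusted p = 0.013, chromosome 5, 124600001 to 124700000) and KL, the klotho gene (−0.21, limma adjusted p = 0.013). None passed at E30 (limma; 2564 at unadjusted p under 0.05) or E180 (1820). Adjusted over the list alone, 3 of 22 luminal bins and 1 of 18 cell cycle bins fell and 1 of 14 fibroblast and endothelial bins rose at R30, and 1 of 38 estrogen-induced bins rose at E180. The R180 count was 48 without T0 replicate 2, 78 without T0 replicate 1, 107 without R180 replicate 3, 146 without R180 replicate 1, 167 without T0 replicate 3 or R30 replicate 3, 187 without R180 replicate 2 and 141 without the block. For R30 it was 0 without any 1 of the T0 or R30 libraries and 3 without E180 replicate 1, for E30 it was 2 without R30 replicate 2, and for E180 it was 2 without E180 replicate 1.

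Single contacts were compared to find bin pairs whose contact changed. At R180 contacts fell inside the GRHL2 locus (GRHL2 with GRHL2 and NCALD, log2 fold change −0.84, edgeR adjusted p = 4.6e-12). They also fell inside and around KDM4B, which encodes a histone demethylase and ER coactivator: with itself −0.87 (edgeR adjusted p = 2.1e-07), with PTPRS −0.92 and with SAFB2 and TINCR −0.97. Contact also fell between KCNMA1 and DLG5 (−0.94, edgeR adjusted p = 0.00298) and between SPMIP7 with ZPBP and GRB10 (−0.81). It rose inside TRPS1, a repressor gene of the GATA family (0.73, edgeR adjusted p = 0.00113), and inside PATJ (0.86, edgeR adjusted p = 0.00869). It also rose between the bin of GATA3 and TAF3 and a bin without a protein-coding gene (0.60, edgeR adjusted p = 0.00113, chromosome 10, 8000001 to 8100000 with 9100001 to 9200000).

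At R180, 6 of 459034 bin pairs rose and 13 fell (edgeR, with 23156 at unadjusted p under 0.05, where DESeq2 called 11). Up to 5 of the falls shared a bin. With balancing biases in the offset 33 passed at R180, 13 of them among the 19 called. The median log2 size of the 19 went from 0.85 to 0.59, all in the same direction, so bin coverage may enter these folds too. At R30, 246 rose and 90 fell (edgeR; 41481 at unadjusted p under 0.05; DESeq2 called 0, with 20545 at unadjusted p under 0.05). The split depended on the scaling, with 31 rises and 34 falls with balancing biases in the offset and 1170 and 76 with TMM library sizes. Of the R30 pairs, contact rose between the CACNG6 cluster and ISOC2 (2.01, edgeR adjusted p = 0.0194), between TCF7L2 and TDRD1 (1.44) and between ACLY and BRCA1 (1.05), and fell between SLIT2 and KCNIP4 (−1.83) and between FNDC3A and FAM124A (−1.98). E30 gave 3 pairs that rose and E180 gave 3 that rose and 1 that fell (edgeR; 19270 and 21065 at unadjusted p under 0.05; DESeq2 called 0 in both). Chosen after their values were seen, pairs at 90.1 Mb of the X chromosome had no contact in any T0 library, so no fold is given for them. The R30 count was 0 without the block, and was 0 without R30 replicate 3 or T0 replicate 3, 1 without T0 replicate 2 and 4 without R30 replicate 2. It was 135 without E180 replicate 3, 149 without E30 replicate 3, 163 without E30 replicate 2, 183 without R180 replicate 3, 218 without E30 replicate 1, 220 without R180 replicate 2, 6649 without R30 replicate 1 and 7381 without T0 replicate 1. The R180 count was 2 without the block, 7 without T0 replicate 1, 10, 11 and 12 without R180 replicates 1, 2 and 3, and 48 without R30 replicate 1. E30 and E180 gave 0 without the block, and 89 and 469 without T0 replicate 1. E30 gave 1 without T0 replicate 2 or 3, E30 replicate 2 or 3, or R30 replicate 2 or 3.

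The series asks how genome structure differs between receptor-positive and receptor-negative cells. The bin of PGR was in the open compartment in T47D (0.95 ± 0.12, SD, n = 3), MCF7 (0.93 ± 0.018, n = 2) and BT474 (1.55 ± 0.083, n = 2), and scored −2.07 ± 0.079 in MCF10 and −0.12 ± 0.17 in SKBR3. The ESR1 bin scored 0.75, 1.23 and 0.37 in T47D, MCF7 and BT474, −0.01 in MCF10 and −0.96 in SKBR3. FOXA1, a pioneer factor gene of luminal cells, scored 1.17, 0.78 and 0.35 in the receptor-positive lines, 0.84 in SKBR3 and −0.50 in MCF10, and TFF1, an estrogen-induced secreted peptide gene, scored 1.78, 1.66, 1.01, 1.57 and 0.22. GREB1 scored higher in the receptor-negative lines, at 1.53 and 1.47 in the MCF10 libraries and 1.43 and 1.20 in the SKBR3 libraries, than in T47D (mean 0.71) and BT474 (mean 0.73). Its MCF7 libraries (1.08 and 1.40) overlapped those of SKBR3. GATA3 scored 0.87, 1.07 and 0.60 in T47D, MCF7 and BT474, 0.81 in SKBR3 and 0.42 in MCF10. FKBP5 scored 1.5 (BT474) to 1.90 (MCF7) in the receptor-positive lines, 1.17 in MCF10 and 1.56 in SKBR3. ZBTB16 scored 0.26 (MCF7) to 1.3 (BT474), against 1.78 in MCF10 and 0.95 in SKBR3. MYC scored 0.63 to 1.38, against 1.40 in MCF10 and 0.43 in SKBR3, and CCND1 scored 2.19 to 3.44, against 2.31 (MCF10) and 2.98 (SKBR3). The limma adjusted p between receptor-positive and receptor-negative lines was 1 for each of these 12 genes. KRT5, a basal keratin gene, scored 3.01 ± 0.40 in MCF10 and 1.17 to 1.76 in the other lines. ERBB2, the amplified receptor gene, scored −1.56 in BT474 and 1.53 to 1.97 elsewhere. Its relative coverage was 14.8 ± 2.3 in BT474 and 7.56 ± 1.2 in SKBR3, against 0.639 to 1.62 in the other lines.

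With the line as the sample, 3 against 2, no bin passed on the compartment score (limma; 1053 at unadjusted p under 0.05) or on insulation (limma; 3.39% of bins at unadjusted p under 0.05). No pair of 541271 passed with edgeR (20852 at unadjusted p under 0.05). PGR differed by 2.24 ± 0.56 (SE, limma adjusted p = 1). Adjusted over the list alone, 1 bin of the estrogen-induced genes, of the luminal markers and of the receptors and cofactors rose, and no bin of the other 9 lists passed. The ERBB2 amplicon was lower in insulation in the receptor-positive lines (6 bins, median −0.43, camera in limma, adjusted p = 0.0256, and 0.986 with an estimated correlation). These 6 bins adjoin each other, so they are not independent values. The ERBB2 bin had high coverage in BT474 (14.8) and SKBR3 (7.56), so the contrast cannot part copy number from receptor status. The basal and mesenchymal markers had a median compartment difference of −0.20 (camera adjusted p = 0.0979). With 1 bin added on each side, the basal markers and the ERBB2 amplicon were lower on the compartment score (camera adjusted p = 0.000714 and 0.0353) and the estrogen-induced genes higher (camera adjusted p = 0.0387). With an estimated correlation and their own bins each had an adjusted p of 0.986. As in the hormone fits, the added bins adjoin, so the p-values with them may be too low. All receptor-positive lines lay above both others in 2160 compartment bins and below in 1913 (14.6% of bins, against 20% by chance), and in 2059 and 2515 insulation bins (16.7% against 20%). Compartment A in all 3 receptor-positive lines and B in both others was found in 172 bins and the opposite in 121. For 4 other groupings of 3 lines in A against 2 in B the numbers were 158 to 240, so 172 was within their range, and 725 bins were B and 790 were A in MCF10 alone. Without SKBR3, 114 compartment bins passed. Without MCF10, 1 compartment bin, 16 insulation bins and 161 pairs passed. Each of these fits leaves 1 receptor-negative line, so its calls describe that line, with the spread taken from the receptor-positive lines alone.

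**Figure D3:**
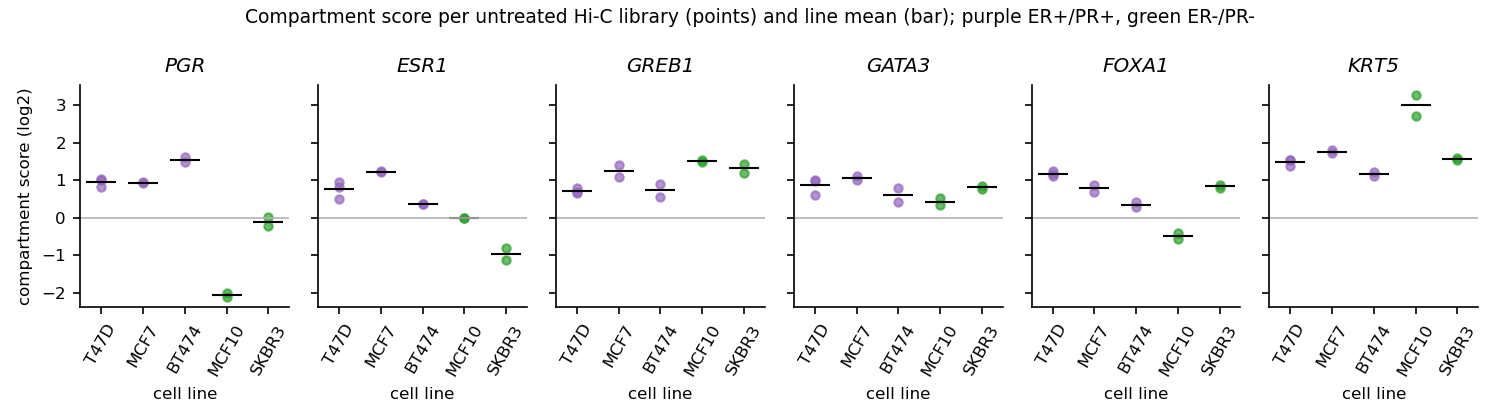
Compartment score (log2) of 6 gene bins in untreated Hi-C libraries of 5 lines, with a point per library and a bar for the line mean, receptor-positive lines in purple and receptor-negative lines in green. PGR lies at 0.93 to 1.55 in the receptor-positive lines and at −2.07 (MCF10) and −0.12 (SKBR3) in the others.

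Regions dense in both receptors were examined for contacts with each other, since the series is about hormone control regions. The 274 receptor cluster bins held 4.80 ER and 4.06 PR peaks per bin. Of the luminal markers, 13 of 24 overlapped a cluster bin, including ESR1, the luminal factor genes FOXA1, GATA3 and XBP1, and the keratin genes KRT7, KRT8 and KRT18. So did 7 of 40 estrogen-induced genes (among them GREB1, TFF1 and CTSD), 3 of 30 progestin-induced genes (CEBPB, FKBP5 and S100P) and 1 of 30 basal markers (FOXC1), against 2.45% of all genes. Their log2 contact enrichment over control bins was 0.04 ± 0.05 at T0, 0.03 ± 0.02 at R30, 0.04 ± 0.02 at R180, 0.06 ± 0.01 at E30 and 0.05 ± 0.02 at E180 (SD, n = 3). Exact two-sided permutation tests against T0 gave p = 0.9, 0.9, 0.4 and 0.7, where 0.1 is the smallest possible. All hormone libraries against T0 differed by 0.01 (exact permutation p = 0.521), and by 0.04 without T0 replicate 1 (exact permutation p = 0.022). Without that library the hormone libraries of its batch have no T0 beside them, so this difference mixes batch with hormone. The within-batch differences for any hormone were −0.04, 0.06 and −0.004, the last with R30 alone. The enrichment was 0.24 in MCF7, 0.19 in BT474, 0.30 in SKBR3 and −0.09 in MCF10 (receptor-positive against receptor-negative lines, exact permutation p = 0.8). The H3K27ac lists come from T47D alone, so cluster and control bins may match less well in the other lines. The R30 value depended on the definition of cluster bins. With at least 5 MCF7 ER peaks (estradiol) and 5 MCF7 PR peaks, R30 differed from T0 by 0.132 (exact permutation p = 0.1). Within batches that difference was 0.144, 0.0715 and 0.181. Under the other settings R30 differed by −0.0205 to 0.0178. With at least 2 peaks of each receptor, E30 differed by 0.0228 (exact permutation p = 0.1).

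Depletion of PR (a stable short hairpin RNA line, shPR) or ER (transient siRNA, siER) was compared with its control to ask whether structure depends on the receptors. No expression values were at hand, so whether PGR and ESR1 transcripts fell was not checked; the compartment score of the PGR bin differed by 0.15 in shPR and that of the ESR1 bin by −0.19 in siER. In siER cells the FKBP5 bin scored 1.38 against 2.24 in the control (−0.86, percentile 0.218 of all bins; −0.21 and percentile 16.1 on the first eigenvector), and the TFF1 bin differed by −0.33. In shPR cells the TFF1 bin scored 1.11 against 1.61 (−0.50, percentile 3.13). Receptor cluster contact was 0.01 in shPR against 0.07 in its control and 0.17 in siER against 0.27. There was 1 library per condition and no test; the SD of compartment differences over all bins was 0.257 for PR and 0.278 for ER.

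On the compartment score, 1 list lay outside the central 95% of 10000 random lists in shPR (blood markers, percentile 99.7) and 3 did in siER (blood markers, 99.1; the ERBB2 amplicon, 99.8; neuronal markers, 98.1). On the first eigenvector these lay at percentiles 92.8 in shPR, and 52.0, 59.0 and 73.2 in siER, inside the central 95%, where the fibroblast and endothelial markers stood apart instead (97.7, against 75.3 on the compartment score). The 6 bins of the ERBB2 amplicon adjoin each other on chromosome 17. The random lists were matched on size and untreated score, not on position, so the amplicon's percentile may overstate how unusual it is. The estrogen-induced genes lay at percentile 32.9 in shPR and 83.9 in siER, and the progestin-induced genes at 71.6 and 24.9. On insulation, the receptor cluster bins had a median difference of −0.02 in shPR (percentile 0.01) and −0.01 in siER (percentile 0.04). Their control bins had −0.02 in both (percentile 0 in both), so this was not particular to cluster bins. Among the gene lists, only the cell cycle genes lay outside the central 95% on insulation (shPR, median −0.05, percentile 1.05).

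ER and PR peaks were compared to see where the receptors bound. In MCF7 cells ER was listed at 6387 peaks at T0 and 36313 after 30 min of estradiol; 90.2% of the former overlapped the latter, and 15.6% of the latter the former. PR was listed at 13446 peaks at T0 and 11983 after 30 min of progestin, of which 4.35% overlapped a T0 peak and 73.6% an ER peak of the estradiol list (1.02% after shifting the peaks). Of the 12914 PR peaks found at T0 alone, 14.5% had a −log10 q of at least 5 and 1.64% overlapped an ER peak of the estradiol list; of the 11462 found with progestin alone, 75.1% and 75.8% did. In T47D cells ER had 15102 peaks in medium with phenol red, 6997 on day 2 and 5887 on day 12 of steroid depletion, and 74.9% and 75.1% of the latter overlapped the first list. The tallest ER peaks near list genes in T47D, in medium with phenol red, lay at MLPH (fold 83.1), GREB1 (fold 72.8) and XBP1 (fold 72.3), all luminal or estrogen-induced genes.

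Of the progestin-induced genes, 66.7% had an MCF7 PR peak (progestin) within 20 kb against 29.4% of other genes (Fisher's exact test, adjusted p = 0.00029). The same held for 67.5% of the estrogen-induced genes and 79.2% of the luminal markers (Fisher's exact test, adjusted p = 1.04e-05 for each) and 68.2% of the receptors and cofactors (Fisher's exact test, adjusted p = 0.00151). A PR peak at T0 lay near 26.7% of the progestin-induced genes against 33.3% of others (Fisher's exact test, adjusted p = 0.687), and with peaks of −log10 q of at least 5 near 16.7% against 5.75% (adjusted p = 0.091). It lay near 70.8% of the luminal markers and 75.0% of the genes of architectural proteins, against 33.3% of others (Fisher's exact test, adjusted p = 0.00175 and 0.00417), and near 0 of the ERBB2 amplicon genes (Fisher's exact test, adjusted p = 0.0272). With peaks of −log10 q of at least 5 the first 2 shares were 12.5% each, against 5.76% of others (Fisher's exact test, adjusted p = 0.428 and 0.482), that of the amplicon was 0 (adjusted p = 1), and the housekeeping genes stood at 25% (adjusted p = 0.0438). T47D ER peaks in medium with phenol red lay near 90.0% of the estrogen-induced genes against 51.1% of others (Fisher's exact test, adjusted p = 4.98e-06), 83.3% of luminal markers, 90.9% of receptors and cofactors and 43.3% of basal markers. ER peaks after estradiol lay near 15.8% of cell cycle genes against 55.7% (Fisher's exact test, adjusted p = 0.00397). Among 84 such tests, ER peaks on day 12 of depletion lay near 6.67% of basal and mesenchymal markers against 33.7% (Fisher's exact test, adjusted p = 0.00417). With peaks of −log10 q of at least 5 the shares were 6.67% and 24.4% (Fisher's exact test, adjusted p = 0.0701).

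With progestin, BRD4, a reader of acetylated histones, had 147063 peaks against 85024 in pair 1 and 2584 against 2757 in pair 2, of which 36.5% and 33.3% overlapped the T0 list. H3K27ac, a mark of active enhancers and promoters, had 62379 peaks against 49318 and 63633 against 54884 (65.7% and 65.5% overlapping T0). Pol II had 467326 peaks after 60 min of progestin against 336649 in the first T0 list and 31941 in the second. Peak numbers move with depth and threshold, and each pair is 1 library against 1.

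The capture libraries enriched chosen regions. In Capture-C, 49 bins held at least 20 times their Hi-C share of contacts, nearly all on chromosome 6 around ESR1, and took 48.6% to 50.9% of contact ends against 0.139% in Hi-C. In capture Hi-C, 41 bins did, with 4.99% to 9.39% against 0.118%. There was 1 library per condition, and no comparison between conditions was tested.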

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

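The direct comparisons, the batch tests, the fits with replicates averaged or summed, the comparison of libraries at equal depth and the use of each test to weigh a pattern were chosen after the results against T0 were seen; the fits without each library and the one with balancing biases were fixed beforehand. R180 and E180 were compared directly, since the same time under 2 hormones could be set side by side: 641 compartment bins differed (315 higher and 326 lower at R180, limma), as did 632 insulation bins (limma) and 121 bin pairs (edgeR). FKBP5 was lower at R180 than at E180 on the compartment score (−0.95, limma adjusted p = 0.0018) and ZBTB16 higher (0.58, limma adjusted p = 0.00238). On insulation, ESR1 was higher (0.31, limma adjusted p = 0.000259) and GATA3 lower (−0.12, limma adjusted p = 0.0337). Between the progestin times, R180 and R30 differed in 32 compartment bins, 135 insulation bins (ESR1 among them, 0.20, limma adjusted p = 0.0181) and 643 bin pairs, of which 114 were higher and 529 lower at R180. R30 and E30 differed in 11 insulation bins and 34 bin pairs, and E180 and E30 in 9 insulation bins. Outside the main measurement, 22 peaks lay on a reporter contig in 13 of 15 T47D lists and 0 in the 4 MCF7 lists and the GM list; whether reads of those lists were mapped to it is not known.

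An effect of progestin stays a hypothesis for the R180 bins, 192 on the compartment score and 286 on insulation. Against a difference between sequencing batches as the cause, the R180 minus T0 compartment differences of the separate batches that held both groups correlated over bins at 0.218, above the highest of the other hormone groups (0.0897). Against replicates 2 and 3 being a library sequenced again, 107 compartment bins passed with the pair averaged, 92 of them among the 192. Against the shallowest library as the cause (R180 replicate 3, 39082372 contacts), bins ranked first by the R180 fit on the other batches had the same sign in the replicate 1 batch, which lacks that library, in 82.8% of cases for the compartment score and 80.1% for insulation, against at most 67.8% for the other hormone groups. How many bins passed still depended on the library left out. It was 33 compartment bins without R180 replicate 3, 1 without T0 replicate 2 (59239263 contacts), 7 without T0 replicate 1 (119983147) and 34 without R180 replicate 1 (120483368). It was 71 without T0 replicate 3 or R30 replicate 3, and 86 to 108 without R180 replicate 2, E30 replicate 1 or 2, or any E180 library. Leaving out the only T0 library of a batch also removes that batch's difference from T0.

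The 336 bin pairs called at R30 were weighed next. They may come from bin coverage that differs between libraries: with the balancing biases in the offset 65 passed, and the median log2 size of the 336 went from 0.40 (25th percentile 0.35) to 0.22 (0.12). Whether they come from replicates 2 and 3 being technical repeats stays open. With these summed 0 passed, but in a fit with fewer samples, in which all 336 pairs kept their direction at a median size of 0.35. At equal depth 7.69% of 26 pairs of libraries from different groups and batches differed less than T0 replicates 2 and 3, and 11.5% less than those of R30. The comparison at equal depth cannot see a likeness in contacts inside a bin. These were 24.3% in both T0 replicates 2 and 3, and 28.5% and 28.6% in those of R30. Leaving out T0 replicate 1 gave 7381 pairs and leaving out R30 replicate 1 gave 6649. Leaving out R30 replicate 3 or T0 replicate 3 gave 0, T0 replicate 2 gave 1 and R30 replicate 2 gave 4. Leaving out E180 replicate 3, E30 replicate 1, 2 or 3, or R180 replicate 2 or 3 gave 135 to 220. R30 replicate 3 and T0 replicate 3 share a batch with no other hormone library, so leaving out either takes both out of the contrast. Of the 336 pairs, 184 of 246 rises and all 90 falls had the same sign in every batch, but the fit that called them used these batches. An early effect of progestin stays open and untested.

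Splits of the 6 libraries of each hormone comparison into groups of 3 number 10, too few for a share under 0.05. For R180 the real split gave 192 compartment bins against 1 for the highest other split, 286 insulation bins against 0 and 19 bin pairs against 52. For R30 it gave 0 compartment bins against 26, 6 insulation bins against 9 and 336 pairs against 2130. The split with 2130 pairs exchanges R30 replicate 1 with T0 replicate 1, so it sets the R30 minus T0 difference of replicates 2 and 3 against that of replicate 1. Each batch lies on both of its sides, and a count several times the real one points to a structure of the samples other than a plain difference between batches. Contacts inside a bin were 28.5% and 28.6% in R30 replicates 2 and 3, against 24.3% in both those of T0. In replicate 1 they were 25.4% at R30 and 25.3% at T0. E180 replicates 2 and 3, at 24.6% and 24.3%, lay near T0. E30 replicates 1 to 3, at 28.6%, 28.2% and 27.9%, lay above T0 in each replicate, and E30 gave 3 pairs. A raised share in all replicates thus need not bring many called pairs. Whether this difference at R30 gave the 2130 pairs was not tested. For E30 the real split gave 0 compartment bins, 0 insulation bins and 3 pairs against 0, 0 and 4, and for E180 it gave 0, 0 and 4 against 0, 0 and 141, where the split with 141 pairs also exchanges the replicate 1 libraries.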

How the results depend on the processing

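Fits with replicates 2 and 3 averaged or summed and the line compartment fit with scores at the same SD were added after seeing the data; the other alternatives were fixed before the data were examined. Where a value below differs from the reported one, the cause was not tested unless stated. At R180, 120 compartment bins passed with distances over 2 Mb only (97 of the 192 among them) and 107 with replicates averaged. Without the block 216 passed, and with the first eigenvector 204, of which 68 were among the 192. R180 insulation gave 67 bins with a 300 kb window, 868 with a 1 Mb window and 141 without the block (paired by batch in the reported fit). R30 insulation gave 2, 14 and 0 bins with the 300 kb window, the 1 Mb window and replicates averaged. E30 insulation gave 2 without the block and 2 with the 1 Mb window, and E180 insulation gave 1 under each of these and 1 with replicates averaged.

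Without the block, bin pairs numbered 0 at R30, 2 at R180, 0 at E30 and 0 at E180. With balancing biases in the offset they numbered 65 (31 rises and 34 falls), 33 and 5 at R30, R180 and E30, and with the DESeq2 Wald test 0, 11, 0 and 0 at R30, R180, E30 and E180. TMM library sizes gave 1246 at R30 (1170 rises and 76 falls), with 288 of the 336 among them. Replicates 2 and 3 summed gave 0 at R30, 1 at E30 and 1 at E180. A mean count of at least 30 gave 0 at E30 and E180, and no count filter gave 10 at E180. The R180 pairs held 16 calls with replicates summed and 18 with TMM. Leaving out the block moved no other count by over 1.5 times.

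Leaving out each library in turn gave 1 (without T0 replicate 2) to 178 R180 compartment bins, 0 to 1 at E30 and 0 to 1 at E180, and 0 throughout at R30. For insulation it gave 0 (without any 1 T0 or R30 library) to 7 at R30, 48 (without T0 replicate 2) to 280 at R180, 0 to 2 at E30 and 0 to 2 at E180. For bin pairs it gave 0 (without R30 replicate 3 or T0 replicate 3) to 7381 (without T0 replicate 1) at R30. It gave 7 (without T0 replicate 1) to 48 (without R30 replicate 1) at R180, 1 to 89 (without T0 replicate 1) at E30 and 3 to 469 (without T0 replicate 1) at E180. Leaving out each line gave 0 to 114 compartment bins (without SKBR3), 0 to 16 insulation bins and 0 to 161 pairs (both without MCF10). Receptor cluster contacts ranged from −0.02 to 0.03 at R30, −0.02 to 0.03 at R180, 0.01 to 0.06 at E30, −0.00320 to 0.05 at E180, and −0.00857 (without T0 replicate 2) to 0.0409 for any hormone (0.0409 without T0 replicate 1, exact permutation p = 0.022, other values from p = 0.401 to 0.923). Between lines they ranged from 0.02 to 0.08 without 1 library, and leaving out a whole line gave −0.14 (without MCF10) to 0.24 (without SKBR3).

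Of the 20 bins named on the R180 compartment score, 20 passed at the same SD, 19 over 2 Mb, 19 averaged, 18 without the block, 10 with the eigenvector, 6 without T0 replicate 1 and 1 without T0 replicate 2. Of the 24 named on R180 insulation, 22 passed with replicates averaged, 17 with the 1 Mb window, 14 without the block, 12 without T0 replicate 2 and 8 with the 300 kb window. Of the 20 pairs named at R30, 0 passed without the block or summed and 4 with biases, and of the 15 at R180, 1, 13 and 11. None of these named values reversed. Gene lists past the camera threshold numbered 0 with an estimated correlation and 10 with 1 bin added on each side. Among the 10 were the progestin-induced genes on the compartment score at R30 (camera adjusted p = 0.0321) and R180 (camera adjusted p = 0.0414). The added bins adjoin, so the p-values of these 10 may be too low at the preset correlation.

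With peaks of −log10 q of at least 5, the shares of peaks overlapping the earlier list were 12.2% (MCF7 ER), 84.7% and 79.9% (T47D ER, days 2 and 12) and 79.1% and 75.1% (H3K27ac). The log2 ratio of MCF7 PR peak numbers, −0.17 as reported, reversed to 1.99, because 2290 of 13446 T0 peaks reached that threshold against 9090 of 11983 with progestin. With a reciprocal overlap of 50% the shares were 9.25% (MCF7 ER), 3.36% (MCF7 PR), 45.4% (PR in ER), 59.9% and 59.0% (T47D ER), 23.3% and 16.3% (BRD4) and 45.7% and 33.0% (H3K27ac). Leaving out pair 1 or 2 gave log2 ratios of −0.0934 (reversed, without pair 1) to 0.79 for BRD4 and 0.21 to 0.34 for H3K27ac. On the first eigenvector, 0 lists stood apart in shPR and 1 in siER, the fibroblast and endothelial markers (97.7), which is none of the 3 reported (52.0, 59.0 and 73.2 for the blood markers, the ERBB2 amplicon and the neuronal markers). At 50 times the Hi-C share, 4 capture Hi-C bins remained of 41. The alternative that limits contacts between chromosomes was not run, since the matrices hold none, and leave-one-out fits assume that a group with fewer libraries varies like the others. With the real libraries' depth and the fitted trend in spread, 1.49% of simulated R180 pairs changed 1.3-fold and 60.6% of those changed 2.5-fold were recovered, with 6 false calls. The simulated libraries were independent, so these values need not hold for the real ones. Whether depth sets the limit on recovery was not tested.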

Other observations

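The tests on PR peaks and on BRD4 peaks in bins that rose in compartment score were set out before their values were seen. For BRD4 the measure set out was peaks found with progestin and not without, whereas the one given below is a difference of peak numbers. The tests on ER and CTCF peaks, and on BRD4 peaks in other bins, were chosen after the changed bins were seen. The receptor cluster bins passed the insulation test at R180 more often than their control bins: 3.73% (2 rose and 8 fell) against 1.20% of control bins and 1.05% of all bins. The cluster bins of GREB1 (rose) and KRT7 (fell) were among those that passed. Those of GATA3 and FOXA1 did not pass, and the ESR1 bin that passed was not a cluster bin. On the compartment score 0.73% of cluster bins passed, against 0.26% and 0.687%. Whether these shares differ was not tested. The bin of PGR had a relative coverage of 2.72 in BT474, and that of MYC 8.57 in SKBR3.

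The Pol II sample that belongs to no group had 24783 peaks, of which 15282 had a −log10 q of at least 5, with a median fold of 4.69, and 74.3% of its peaks overlapped the second T0 list. The CTCF list of the GM line had 39856 peaks.

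If PR binding marks where structure changes with progestin, bins that changed at R180 should hold more MCF7 PR peaks than matched random bins. For these tests 1 bin was taken per run of adjacent bins, from 94 runs that rose and 53 that fell in compartment score and from 89 and 108 in insulation. Such bins that rose in compartment score held 0.574 PR peaks per bin against 0.369 in matched sets (percentile 99.2 of 10000), and bins that rose or fell in insulation held 0.742 against 0.477 (percentile 99.2) and 0.722 against 0.554 (percentile 96.5), consistent with that idea. Bins that fell in compartment score held 0.509 against 0.504 (percentile 51.6), which argues against it for these bins as a set, though single bins among them held PR peaks (1 at FKBP5 and 2 at GRHL2). The number of BRD4 peaks with progestin minus that without, in pair 1, was 2.23 per bin against 1.62 in matched sets where the compartment score rose (percentile 95.1) and 1.09 against 1.99 where it fell (percentile 3.93). For insulation it was 3.17 against 2.34 where contact rose (percentile 96.7) and 2.55 against 3.24 where it fell (percentile 5.58). In the bins that rose in compartment score, MCF7 ER peaks were at percentile 64.2 and T47D ER peaks at 20.2. These PR peaks come from MCF7 cells, so whether PR occupies the same bins in T47D stays open.

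With the same 1 bin per run, CTCF peaks of the GM line were fewer than in matched bins where the compartment score rose (0.894 against 1.17 per bin, percentile 1.73) and where it fell (0.755 against 1.34, percentile 0.02). At bins that changed in insulation they were at percentiles 94.3 (rose) and 87.0 (fell).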
